A study of Mus musculus with 64 samples.

How the data were processed

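RNA from the striatum and the cortex of 32 mice aged 6 months was sequenced, giving 64 libraries in 8 groups of 8, with 4 females and 4 males in each group. The labels give 4 genotypes on a C57BL/6 background. They are wild type (WT), heterozygous Q140 knock-in mice (Q140), Q140 mice that also carry Rgs9-Cre (Q140Cre), and Q140 mice with Rgs9-Cre and floxed Msh2 on both alleles (Q140CreMsh2fl). Libraries were named by group, sex (F or M) and number. The same animal gave the striatal and the cortical library of the same name, while the same number in different genotypes is a different animal. The submitters updated the genotypes of some records after the first deposit, and the current labels were used.

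Per the labels, RNA was extracted with RNeasy columns and libraries were made with the Illumina TruSeq stranded kit. The submitters' processing notes name STAR 2.7.5c, SAMtools 1.10 and HTSeq 0.12.3 with the builds GRCm38 and mm10, without the role or settings of each tool, the gene annotation or the strand setting. The deposited count table held whole read counts per Ensembl gene, not normalized, for 48795 genes with 1 column per library. The deposited FPKM table was made by the authors from these counts. Each FPKM value was the count divided by a length that was constant per gene and by the library total over the listed genes, to within a relative deviation of 1.2e-06, and 100% of the implied lengths were whole numbers within a tolerance of 0.01. No gene was without an identifier (0 entries) and 0 value columns were unused. There were 134 symbols that belonged to more than 1 identifier, and these were kept apart by identifier. Since neither strand nor the treatment of shared reads was stated for the counting, values of overlapping and antisense genes and of near-identical copies (protocadherin beta genes, pseudogenes, predicted genes such as Gm6969, and mitochondrial genes with nuclear copies) are uncertain.

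Library totals were 25.4 to 41.5 M counts, with a mean of 33.3 M (M, mega). Counts were analysed in R 4.3.3 with edgeR 4.0.16. Each tissue was fitted alone, with all of its 32 libraries, filterByExpr over the 4 genotypes, TMM scaling, and a quasi-likelihood model with genotype and sex. This left 18075 genes in the striatum and 18100 in the cortex, with a biological coefficient of variation of 0.0763 and 0.0657. Within each tissue 5 comparisons were tested, each 8 animals against 8, with two-sided quasi-likelihood tests and Benjamini-Hochberg adjustment. Genes with an adjusted p under 0.05 are said to have risen or fallen. The standard error of a log2 fold change was its size divided by the square root of the quasi-likelihood F statistic. The difference between tissues was tested in a fit of all 64 libraries over 18965 genes, with sex and sex by tissue as covariates, and the difference between sexes in a striatal fit of genotype by sex groups. Levels in CPM were computed with TMM-scaled library sizes and are given as mean ± SD. Replicates are separate animals, so the p-values describe variation between animals. Litter and cohort are not stated. In the labels some animal names share a leading number across WT, Q140 and Q140Cre, and none do between Q140CreMsh2fl and another genotype, so a litter or cohort difference could lie along with floxed Msh2. Strain and mitochondrial background beyond the C57BL/6 of the labels were not tested.

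A Q140 signature score was computed for each library as the mean log2 CPM (prior count 2) over the genes called between Q140 and WT in that tissue, each taken with the sign of its change and centred on the 16 Q140 and WT libraries. Q140Cre and Q140CreMsh2fl libraries, which were not among the libraries compared to define the signature though they entered the filter, scaling and dispersions of the fit, were compared by a two-sided exact permutation test over all 12870 splits of 8 against 8. The interval of the difference is a bootstrap over libraries with 10000 draws.

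The 23 gene lists were written from general knowledge. They cover spiny projection neurons (SPN; shared, direct pathway and indirect pathway genes), striatal interneurons, cortical excitatory neurons, thalamic and other neighbouring neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial cells, mural cells, choroid plexus and ependyma, reactive glia, clustered protocadherin beta genes, developmental transcription factors that are Polycomb targets, immediate early genes, voltage-gated ion channels, mismatch repair, p53 and DNA damage, interferon response, cholesterol biosynthesis, and heat shock. Scn4b and Kcnip2 stand in both the shared SPN list and the ion channel list, and Gfap in both the astrocyte and the reactive glia list. Rgs9, which the Cre line alters, is a member of the shared SPN list, and Msh2 of the mismatch repair list. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 and again with an estimated correlation, each adjusted over the 23 lists. For each list, calls adjusted over all tested genes and calls adjusted over the list alone were counted.

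Genes were named by a rule. Msh2, Htt and Rgs9 were named in every comparison. In each comparison the 10 largest rises and the 10 largest falls were taken among genes past the threshold with a mean of at least 1 CPM in 1 of the groups and a symbol other than a predicted gene. Each list gave up to 4 members with the smallest p. Xist, Ddx3y, Uty and Kdm5d were read as a check of the sex labels, and Drd1, Adora2a, Slc17a7 and Neurod6 as a check of the tissue labels. The groups, comparisons, lists, naming rule and settings to vary were fixed before the data were examined, except where a choice is said to have been made later.

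The fit was tested on simulated negative binomial counts with the means, dispersions and library sizes of the real data and no difference between groups other than 200 genes of at least 1 CPM, which were changed by 1.2, 1.5 or 2-fold. Of the changed genes, 92.5% were called at 1.5-fold for Q140 vs WT in the striatum and 94% for Q140CreMsh2fl vs Q140Cre in the striatum, and 49.3% and 58.2% at 1.2-fold. With 200 changed genes the adjustment is stricter than where 4928 genes were called, as in the real Q140 vs WT striatum. Genes were also simulated independently of each other, so these shares need not hold for the real data. In the sex differences, 67.2% and 64.2% were called at 1.5-fold, and 13.4% and 20.9% at 1.2-fold. No called gene had the wrong sign (0), and each run gave 4 to 14 calls among unchanged genes. Libraries were also checked for duplicates, and none was found. As a check of the pairing of tissues, deviations from the group means were correlated between the striatal and cortical libraries of each animal. The median correlation was 0.23 with the same animal and -0.01 with other animals, and 21 of the 32 animals correlated best with their own library.

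The settings varied by plan were RLE size factors, DESeq2 1.42.0, no filter on low counts, a stricter filter, no sex covariate, plate column as a covariate, a fit of the 16 compared libraries alone, limma on log2 of FPKM plus 0.1 or 1, the replicate number or the animal as a block, other definitions of the signature, list tests with an estimated correlation, and leaving out each library in turn. Plate positions come from the labels. After the data were seen, a fit without 3 striatal libraries that stood apart (Q140 F1, Q140 M1 and Q140Cre F1) and a fit with scores of 2 neighbour tissue lists as covariates were added, with a test of the choroid plexus list in Q140Cre vs Q140 without Q140 F1. Repeat length and splicing could not be read from gene counts and were left out.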

Results

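The data were read counts per gene from 64 RNA-seq libraries of mouse striatum and cortex at 6 months. They came from wild-type mice (WT), mice with 1 Q140 allele of Htt (Q140), a knock-in with an expanded CAG repeat that models Huntington's disease, Q140 mice that also carried Rgs9-Cre (Q140Cre), a recombinase directed to striatal projection neurons, and Q140 mice with Rgs9-Cre and floxed Msh2 on both alleles (Q140CreMsh2fl). Each of the 8 groups of genotype and tissue held 8 libraries from separate animals, 4 female and 4 male. Striatal libraries held on average 31.1 M (mega) counts in WT (28.2 to 35.8), 31.2 in Q140 (28.5 to 33.9), 34.5 in Q140Cre (30.7 to 38.7) and 32.8 in Q140CreMsh2fl (28.1 to 37.5). Cortical libraries held 33.3 M counts in WT (29.8 to 38), 34.1 in Q140 (26.9 to 39.5), 34.6 in Q140Cre (29.5 to 38.6) and 34.4 in Q140CreMsh2fl (25.4 to 41.5). The quasi-likelihood tests on genes were two-sided, and adjusted p-values come from edgeR unless another test is named. Gene changes are log2 fold changes, 8 animals against 8.

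The genes that the mouse lines alter were read first. Msh2, a DNA mismatch repair gene (ENSMUSG00000024151, GRCm38 chromosome 17, 87672330 to 87723713, plus strand), measured 23.5 ± 1.06 CPM (SD, n = 8) in the WT striatum, 25.7 ± 1.49 in Q140, 25.5 ± 1.34 in Q140Cre and 25.6 ± 1.05 in Q140CreMsh2fl. In the cortex it measured 32.5 ± 0.902, 32.8 ± 1.84, 31.4 ± 1.81 and 36.7 ± 2.54 CPM in the same order. Q140CreMsh2fl differed from Q140Cre by a log2 fold change of 0.01 (SE 0.0369, adjusted p = 0.955) in the striatum and 0.22 (SE 0.0399, adjusted p = 0.0115) in the cortex. Counts per gene include reads from exons that excision leaves in place, and Cre acts in part of the cells, so the Msh2 count checks little of the genotype labels. Against WT, Msh2 in the striatum was higher in Q140 by 0.13 (adjusted p = 0.00781), in Q140Cre by 0.12 (adjusted p = 0.0151) and in Q140CreMsh2fl by 0.13 (adjusted p = 0.014), and in the cortex it was higher in Q140CreMsh2fl by 0.18 (adjusted p = 0.048). That last call ended with RLE (adjusted p = 0.0512), without a low-count filter (adjusted p = 0.0636) and on log2(FPKM + 1) (adjusted p = 0.05).

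Htt (ENSMUSG00000029104, GRCm38 chromosome 5, 34761740 to 34912534, plus strand) measured 212 ± 5.97 CPM in the WT striatum, 196.5 ± 17.4 in Q140, 197 ± 10.5 in Q140Cre and 206 ± 8.37 in Q140CreMsh2fl, and 257 ± 6.54, 234.5 ± 5.79, 232 ± 17.6 and 232 ± 11.6 in the cortex. Its change passed the test in Q140 vs WT in the striatum (log2 fold change -0.11, SE 0.0422, adjusted p = 0.0457) and in Q140Cre vs WT in the cortex (-0.15, adjusted p = 0.0333). Without Q140 striatum M1, which measured 154 CPM, the former was -0.07 (SE 0.029, adjusted p = 0.0893), and it did not pass without a low-count filter (adjusted p = 0.0655) or on log2(FPKM + 0.1) (adjusted p = 0.428). The latter did not pass on log2(FPKM + 0.1) (adjusted p = 0.0703). In the Q140Cre cortex Htt measured 219.9 ± 18.7 CPM in the 4 females, with a lowest value of 197, and 243.5 ± 2.21 in the 4 males. Its values in the other comparisons with WT were -0.11 (adjusted p = 0.0528) for Q140Cre and -0.04 (adjusted p = 0.555) for Q140CreMsh2fl in the striatum, and -0.13 (adjusted p = 0.217) and -0.15 (adjusted p = 0.063) for Q140 and Q140CreMsh2fl in the cortex. Rgs9, a regulator of G protein signalling of striatal projection neurons (ENSMUSG00000020599, GRCm38 chromosome 11, 109225355 to 109298129, minus strand), measured 902 ± 62.2 CPM in the WT striatum, 573 ± 30.5 in Q140, 446 ± 25.8 in Q140Cre and 516 ± 40.4 in Q140CreMsh2fl. In the cortex it measured 7.83 ± 0.909, 7.4 ± 0.633, 5.64 ± 0.674 and 5.76 ± 0.43 CPM. Rgs9 fell in Q140 against WT in the striatum (-0.65, SE 0.045, adjusted p = 1.02e-13) and in Q140Cre against Q140 in both tissues. The latter change was -0.36 (SE 0.0449, adjusted p = 3.74e-05) in the striatum and -0.39 (SE 0.0738, adjusted p = 0.026) in the cortex, where it did not pass on log2(FPKM + 0.1) (adjusted p = 0.0662) or log2(FPKM + 1) (adjusted p = 0.0625). Against WT, Rgs9 measured -1.02 (adjusted p = 2.77e-18) in Q140Cre and -0.81 (adjusted p = 7.75e-15) in Q140CreMsh2fl in the striatum. It rose in Q140CreMsh2fl against Q140Cre in the striatum by 0.21 (SE 0.0449, adjusted p = 0.0122) and measured 0.03 (adjusted p = 0.903) in the cortex.

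**Figure D1:**
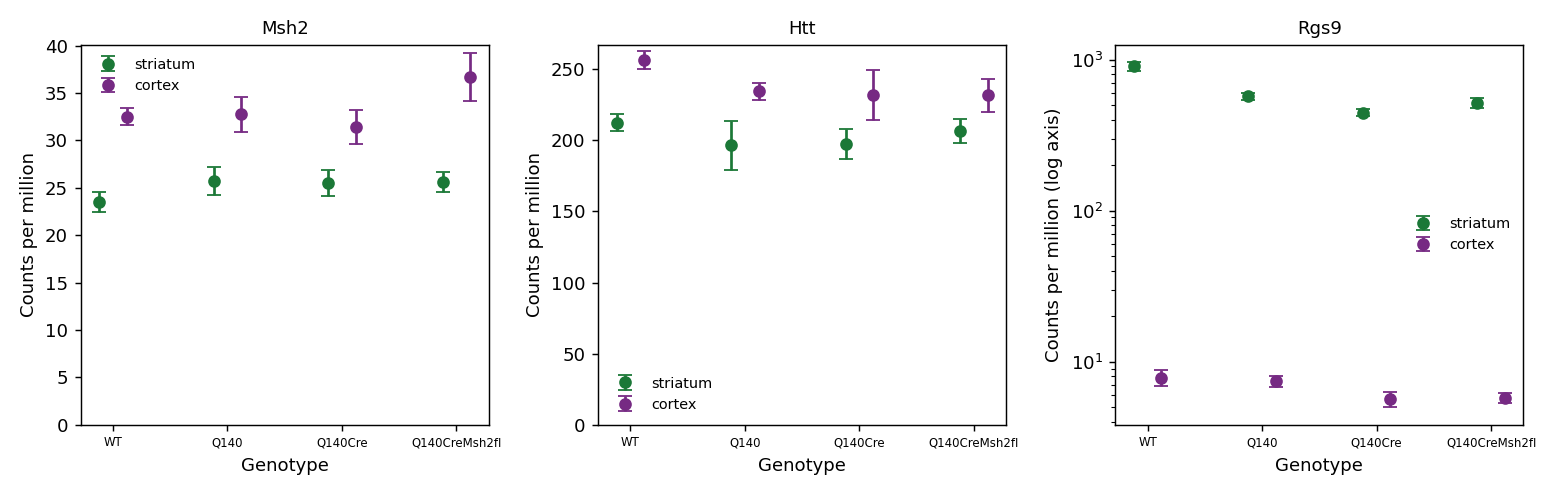
Group means of Msh2, Htt and Rgs9 in CPM by genotype, in the striatum and the cortex, with bars of 1 SD over 8 animals and a log axis for Rgs9. Striatal Rgs9 has a mean of 902 CPM in WT and 446 in Q140Cre, and cortical Msh2 is highest in Q140CreMsh2fl with a mean of 36.7.

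The sex and tissue labels held in all 64 libraries. Xist, which silences the X chromosome in females, measured 1110 to 1610 CPM in female striatum and at most 1.67 in male striatum, and 868 to 1130 against at most 1.89 in the cortex. The Y-linked Ddx3y measured 63.5 to 82.7 CPM in male striatum and at most 0.184 in female striatum, and Uty and Kdm5d at least 19.1 and 45.4 in male and at most 0.0919 and 0.0635 in female striatum, and at least 15.9 and 32.3 in male and at most 0.0337 and 0.0771 in female cortex. Drd1, a dopamine receptor of projection neurons, had group means of 225 to 365 CPM in the striatum and 6.4 to 6.7 in the cortex, and Adora2a 252 to 448 CPM in the striatum. Slc17a7, the glutamate transporter of cortical neurons, measured 1242 to 1290 CPM as group means in the cortex and 4.27 to 8.36 in the striatum, and Neurod6 at most 0.601 CPM as a striatal group mean. Single striatal libraries held more Slc17a7, with 40 CPM in Q140 F3, 21.1 in Q140Cre M2 and 18.5 in Q140CreMsh2fl M4. The lowest cortical library held 1200 CPM.

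What the Q140 allele changed at 6 months was asked in Q140 vs WT. In the striatum the genes that mark its projection neurons were lower. Of the 30 shared SPN genes, 29 fell and 1 (Strip2) rose, with a median log2 fold change of -0.456. The falls included the sodium channel subunit Scn4b (-1.23, SE 0.054), the phosphodiesterase Pde1b (-0.62, SE 0.03), the dopamine signalling gene Ppp1r1b (-0.67, SE 0.033) and the adenylyl cyclase Adcy5 (-0.69, SE 0.037). Of 6 indirect pathway genes 5 fell, among them the adenosine receptor Adora2a (-0.79, SE 0.041), the enkephalin precursor Penk (-1.06, SE 0.058), the dopamine receptor Drd2 (-0.62) and Gpr6 (-0.67). The 8 direct pathway genes moved apart, with 4 falls that included Drd1 (-0.67, SE 0.044) and Chrm4 (-0.64) and 3 rises that included Isl1 (0.40) and Tac1 (0.20). Of 16 voltage-gated ion channel genes 11 fell and 1 rose, with Kcnab1 at -0.58, Kcnh4 at -0.87 and Kcnj4 at -0.46.

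Members of other lists also passed in the Q140 striatum, where 27.3% of all tested genes did. Of 21 clustered protocadherin beta genes, neuronal adhesion molecules, 19 rose and 0 fell, with Pcdhb3 at 0.90, Pcdhb20 at 0.57, Pcdhb22 at 0.67 and Pcdhb12 at 0.60. Of 12 measured developmental transcription factors 4 rose and 1 fell, with Wt1 at 4.17, Onecut1 at 3.24 from a WT mean of 0.0418 CPM, Sox11 at 0.86 and Foxg1 at -0.30. Of 16 immediate early genes, which follow neuronal activity, 10 fell and 0 rose, with Egr2 at -1.62, Egr4 at -0.75, Homer1 at -0.66 and Egr3 at -0.60. Of 12 oligodendrocyte genes 6 fell, with Plp1 at -0.29, Mal at -0.29 and Cldn11 at -0.26, and of 12 microglial genes 8 fell, with Siglech at -0.22, P2ry12 at -0.21 and Cx3cr1 at -0.19. Of the 7 mural cell genes 4 fell, with Tagln at -0.88. Smaller numbers fell among endothelial cells (4 of 10; Cdh5 -0.19), astrocytes (3 of 12; Slc1a2 -0.22), reactive glia (2 of 12; Apoe -0.14 and C4b -0.28), striatal interneurons (1 of 10; Nos1 -0.18) and thalamic neurons (1 of 8; Synpo2 -0.30). Cortical excitatory genes had 2 rises of 11 (Mef2c 0.15 and Cux2 0.28) and oligodendrocyte precursors 0 calls of 8. Of 22 cholesterol synthesis genes 5 fell and 1 rose, with the regulator Srebf2 at -0.27 and the rate-limiting Hmgcr at -0.19. Of 18 p53 and DNA damage genes 3 fell (Plk2 -0.29, Gadd45a -0.59 and Cdkn1a -0.49) and 1 rose (Eda2r 0.61). Heat shock genes had 2 rises of 12 (Hspa8 0.29 and Hsp90aa1 0.15), interferon genes 1 of 13 (Stat1 0.22) and mismatch repair genes 1 of 14 (Msh2).

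In this comparison 9 of the 23 lists passed the list test at the preset correlation and 4 passed with an estimated one. Those 4 were the shared SPN genes (adjusted p = 2.55e-68 preset and 3.97e-05 estimated), the indirect pathway (1.05e-21 and 1.9e-06), the ion channels (2.28e-18 and 4.97e-05) and the protocadherins (1.51e-16 and 0.00432). The other 5 lost the call, with adjusted p = 0.414 for the immediate early genes, 0.414 for microglia, 0.562 for oligodendrocytes, 0.111 for mural cells and 0.0929 for the developmental factors with an estimated correlation. The direct pathway had adjusted p = 0.056 preset. Adjusted over the list alone, falls numbered 29 for the shared SPN genes, 5 for the indirect and 5 for the direct pathway, 13 for ion channels, 13 for immediate early genes, 10 for microglia and 7 for oligodendrocytes, and 20 protocadherins rose.

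Between Q140 and WT striatum 4928 of 18075 genes passed the test, 2431 higher and 2497 lower, of which 603 changed at least 1.5-fold and 147 at least 2-fold. The near-even split depends on the scaling, as log2(FPKM + 0.1), which has no TMM scaling, gave 5075 rises and 1578 falls. The largest falls were Ifi27l2b (-4.05), Wnt8b (-2.98), Aoah (-2.96), the insulin gene activator Mafa (-2.82), Tmem114 (-2.81), Gpx6 (-2.45), Tmprss6 (-2.14), the stress peptide Crh (-2.08), Cpne9 (-2.08) and Slc4a11 (-2.08). The largest rises were Wt1 (4.17), the thyroid hormone carrier Ttr (3.5), Mfrp (2.51), Folr1 (2.30), Tmem72 (2.09), Otx2 (1.88), F5 (1.84), Dsp (1.78), Prlr (1.69) and Sfmbt2 (1.67). In 1 library, Q140 striatum F1, Ttr, a choroid plexus gene, measured 1320 CPM against 1.46 to 54.3 in the other striatal libraries. Without it Ttr measured 0.54 (adjusted p = 0.524), 3 of these 10 rises passed (Wt1 4.10, Dsp 1.59 and Sfmbt2 1.67), all 10 falls passed, and of the 6 genes of the choroid plexus and ependyma list 1 rose in place of 4.

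**Figure D2:**
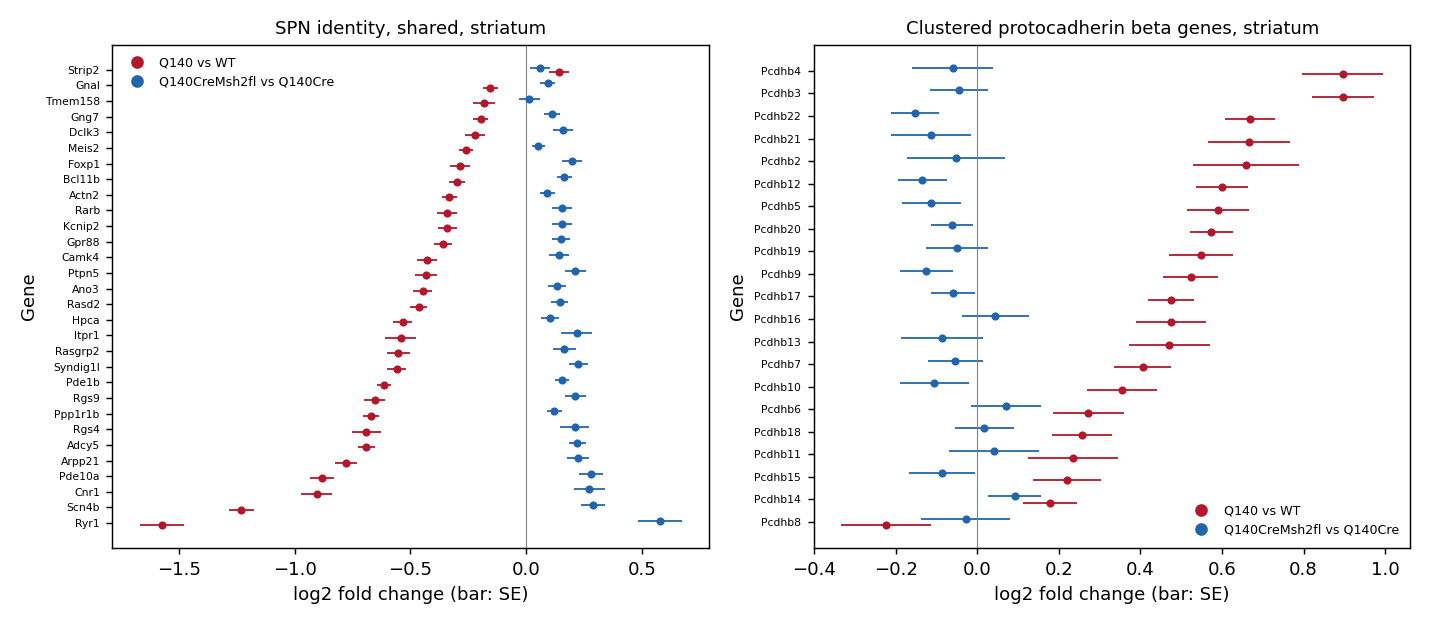
Log2 fold change with its SE for each of the 30 shared SPN genes and the 21 protocadherin beta genes in the striatum, in Q140 vs WT and in Q140CreMsh2fl vs Q140Cre. The SPN genes have medians of -0.456 and 0.156, and protocadherins of 0.475 and -0.06.

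Whether floxed Msh2 in mice with Rgs9-Cre and Q140 changed expression was asked in Q140CreMsh2fl vs Q140Cre. In the striatum SPN genes were higher in Q140CreMsh2fl. Of the 30 shared SPN genes 15 rose and 0 fell, with a median of 0.156, and 27 rose adjusted over the list alone. The calcium channel Ryr1 rose by 0.58 (SE 0.094, adjusted p = 0.00132), Adcy5 by 0.22 (SE 0.037, adjusted p = 0.00192), Scn4b by 0.29 (SE 0.053, adjusted p = 0.00366) and Syndig1l by 0.22. Of 6 indirect pathway genes 4 rose, Penk by 0.28, Drd2 by 0.22, Gpr6 by 0.21 and Adora2a by 0.19 (SE 0.041, adjusted p = 0.0144), and of 8 direct pathway genes Drd1 rose, by 0.20 (SE 0.044, adjusted p = 0.0164). Drd1 measured 257.5 ± 17.4 CPM in Q140CreMsh2fl, 225 ± 13.7 in Q140Cre and 365 ± 16.5 in WT. Of 16 ion channel genes 4 rose and 0 fell, Scn4b with Kcna4 (0.16), Kcnk2 (0.19) and Kcnab1 (0.15), and 10 rose and 1 fell adjusted over the list alone. The haemoglobin gene Hbb-bs, a measure of blood in the tissue, had 4.68 ± 7.88 CPM in Q140CreMsh2fl and 11.7 ± 7.01 in Q140Cre (log2 fold change -1.50, SE 0.672, adjusted p = 0.302).

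The largest rises in this comparison were Ccdc170 (1.79, SE 0.46), the signalling gene Wnt8b (1.01, SE 0.24), Gpx6 (0.77, SE 0.17), P2rx6 (0.74), the activin antagonist Fst (0.73, SE 0.12), Emp1 (0.73), Phex (0.72), Shisa2 (0.69), the activin subunit Inhba (0.66, SE 0.12) and Bank1 (0.62). The largest falls were Frem3 (-0.73, SE 0.17), Greb1l (-0.61, SE 0.14), Apitd1 (-0.52), Kazald1 (-0.51), Sfmbt2 (-0.47, SE 0.097), Cox7a2l (-0.43, SE 0.051), Cebpzos (-0.41, SE 0.063), Wnt3 (-0.41), Slc5a5 (-0.37) and Wbscr27 (-0.36). Cox7a2l, a respiratory supercomplex factor, and Cebpzos lie within 10 Mb of Msh2, where 7 of the 263 called genes lay (one-sided Fisher's exact p = 0.000191). Among the other lists, Tagln of the mural cells (0.40) and Synpo2 of the thalamic list (0.26) rose and Onecut1 fell (-1.25, SE 0.33, adjusted p = 0.0411). Foxj1, which marks ciliated ependymal cells, measured 0.39 (SE 0.14, adjusted p = 0.176). The mitochondrial gene mt-Nd1 rose by 0.22 (adjusted p = 0.0199) and mt-Nd5 fell by 0.23 (adjusted p = 0.00884).

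Here 263 genes passed the test, 200 higher and 63 lower, with a median size of 0.221, and 23 changed at least 1.5-fold. Of the 23 lists 5 passed, the shared SPN genes (adjusted p = 8.92e-39), ion channels (6.39e-11), the indirect pathway (1.82e-07), the direct pathway (0.0411) and mural cells (0.034). With an estimated correlation the first 3 kept adjusted p = 0.00213 each, and the direct pathway and mural cells had adjusted p = 0.212 each. The lists that did not pass had adjusted p = 0.0992 for protocadherins (median -0.06, 0 calls), immediate early genes, developmental factors and choroid plexus, and 0.331 to 0.936 for the other 14. Libraries were spread unevenly over plate columns, with 7 of 8 Q140CreMsh2fl libraries in the fourth striatal column and 5 of 8 Q140Cre libraries in the third. With plate column in the model 0 genes passed in edgeR (162 of the 263 at an unadjusted p under 0.05, and all 263 with the same sign), while DESeq2 without plate column called 449. The count was 88 without Q140Cre M4, 109 without Q140Cre F3, 135 without Q140Cre M3, 86 without Q140CreMsh2fl M1, 111 without Q140CreMsh2fl M4, and 162 without Q140CreMsh2fl F3 or M2.

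The Q140 signature score put each library on the scale of the 4928 genes called between Q140 and WT in the striatum. The mean score was -0.158 (SD 0.012) in WT and 0.158 (SD 0.015) in Q140, which are not independent of the choice of genes. It was 0.152 (SD 0.022, n = 8) in Q140Cre and 0.086 (SD 0.024, n = 8) in Q140CreMsh2fl, a difference of -0.066 (95% bootstrap interval -0.087 to -0.046). The two-sided exact permutation p was 0.000155, the smallest that the 12870 splits allow, and all 8 Q140CreMsh2fl libraries lay below the lowest Q140Cre library. The difference was -0.06 in females and -0.072 in males (exact permutation p = 0.0286 in each, the smallest of 70 splits). It amounted to 21.3% of the gap of 0.31 between Q140Cre and WT. The WT libraries helped to choose the genes, so the size of this gap, and the share with it, is not independent of that choice. Of the 263 called genes 227 were in the signature, where independent lists would share 71.7. That figure takes every gene as equally likely to be called, while both lists come from the same fit and favour genes that vary little. All 227 had the opposite sign to Q140 vs WT, with 181 falls followed by rises and 46 rises followed by falls. Of the signature genes 78% had the opposite sign, against 56.6% of the other genes, which are not independent of each other. With plate column beside sex the score difference was -0.066 (SE 0.015). In that fit plate column and genotype are told apart by few libraries, Q140Cre M1 in the fourth column and Q140CreMsh2fl F4 in the first.

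**Figure D3:**
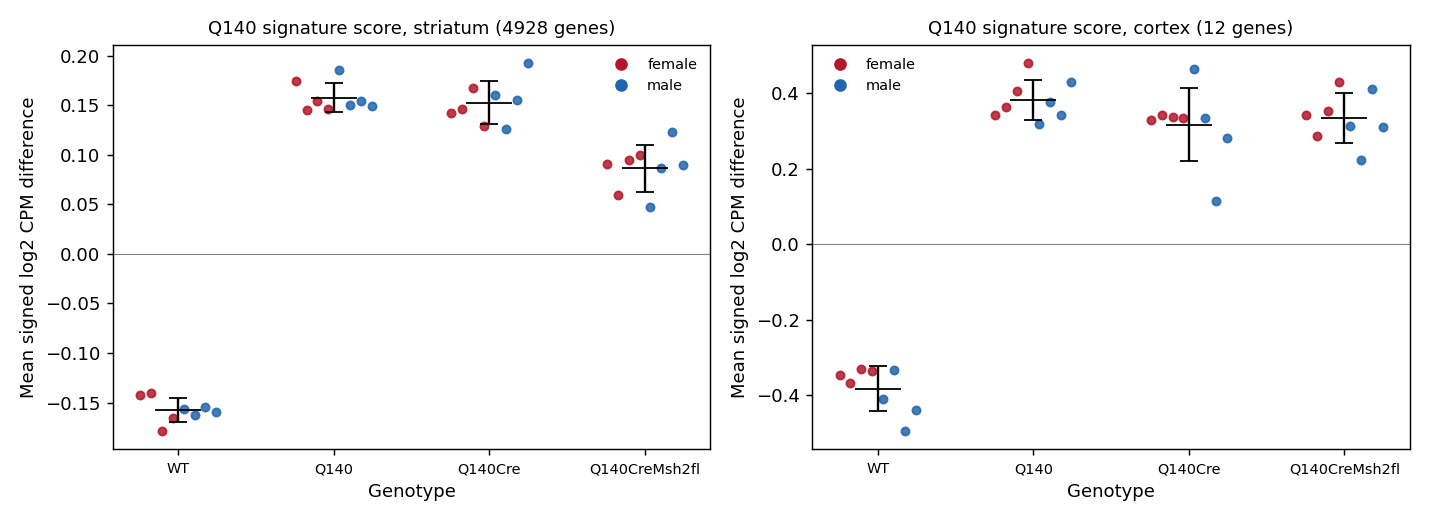
Q140 signature score of each library by genotype, in the striatum (4928 genes) and the cortex (12 genes), with group means and SD. In the striatum the 8 Q140CreMsh2fl libraries lie between 0.047 and 0.123 and the 8 Q140Cre libraries between 0.126 and 0.192.

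Q140Cre vs Q140 asked what Rgs9-Cre changed in Q140 mice. In the striatum Rgs9 fell and was the single gene of 18075 that passed (0 rose), with 1202 at an unadjusted p under 0.05 and 3 called by DESeq2. In the cortex 7 genes passed, and Cacng5 (0.47), Nrbp2 (0.21), Slmo1 (0.20) and Snx32 (0.14) rose while the nuclear import gene Kpna2 (-0.51, SE 0.089), Rgs9 (-0.39) and Synj2bp (-0.21) fell. Kpna2 and Cacng5 lie within 10 Mb of Rgs9 (one-sided Fisher's exact p = 0.00443, and 0.0148 adjusted over the 30 such tests). In the striatum 5 lists passed at the preset correlation, shared SPN genes (adjusted p = 5.29e-09, Rgs9 itself among them), heat shock (6.08e-06), immediate early genes (0.000721), ion channels (0.0274) and choroid plexus (0.0287). All 5 had adjusted p = 0.618 with an estimated correlation. In the choroid list Ttr measured -4.77 (SE 1, adjusted p = 0.204). Without Q140 F1, a setting chosen after the data were seen, this list had adjusted p = 0.392 and Ttr measured -1.61 (SE 0.57, adjusted p = 0.779). In the cortex heat shock genes passed (adjusted p = 0.000198, and 0.935 with an estimated correlation), with Hspb1 at -0.54. The striatal count was 2 without Q140Cre M1 or without Q140 F3, M1 or M3. The cortical count was 349 without Q140 M3, 101 without Q140Cre F1, 82 without Q140Cre M1, 26 without Q140Cre F3 and 13 without Q140Cre M4. It was 4 without Q140Cre M2, 3 without Q140 M1, 2 without Q140Cre F2 or Q140 F3, F4 or M2, and 0 without Q140Cre F4 or M3 or Q140 F1 or M4. Over the 10 other settings the cortical count was 0 to 241, the latter by DESeq2.

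Q140Cre vs WT and Q140CreMsh2fl vs WT gave the distance from WT of mice with both Q140 and Rgs9-Cre. WT carried no Rgs9-Cre, so both comparisons combine the Q140 and Cre alleles, the second with floxed Msh2 too. They share the WT libraries with each other and with Q140 vs WT, so their chance values are shared. In the Q140Cre striatum 29 of 30 shared SPN genes fell and 1 rose (median -0.519), 14 of 16 ion channel genes fell and 1 rose, 13 of 16 immediate early genes fell, 5 of 6 indirect pathway genes fell, and 17 of 21 protocadherins rose and 1 fell. The largest changes included Wt1 (4.48), Capn11 (2.38), Crnde (2.14), Sfmbt2 (1.77) and Tmc3 (1.70) upward, and Ifi27l2b (-4.53), Gpx6 (-2.75), Mafa (-2.72), Tmem114 (-2.57), Cpne9 (-2.22) and the mTOR inhibitor Ddit4l (-2.17) downward. In all 5461 genes passed, 2722 higher and 2739 lower. In the Q140CreMsh2fl striatum 29 of the shared SPN genes fell and 1 rose (median -0.361), 11 ion channel genes fell, 11 immediate early genes fell, 5 indirect pathway genes fell, 7 of 12 oligodendrocyte genes fell, and 17 protocadherins rose and 1 fell. The largest changes included Capn11 (2.77, SE 0.81, with 1.6 ± 1.8 CPM in Q140CreMsh2fl), Tmc3 (1.59), H60b (1.54), and the desmosome genes Dsp (1.52) and Dsg2 (1.37) upward, and Ifi27l2b (-3.47), Aoah (-2.54), Mafa (-2.42), Tmem114 (-1.86), Gpx6 (-1.99) and Ddit4l (-1.63) downward. Here 3673 genes passed, 1695 higher and 1978 lower, and 1339 with plate column in the model. Of the 23 lists 8 passed in each comparison, and 4 in each passed with an estimated correlation, the shared SPN genes (adjusted p = 1.25e-05 and 0.000123), the indirect pathway (1.46e-06 and 4.55e-06), ion channels (2.33e-05 and 0.000209) and protocadherins (0.00989 and 0.00366). Immediate early genes had adjusted p = 0.23 and 0.252 with an estimated correlation.

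**Figure D4:**
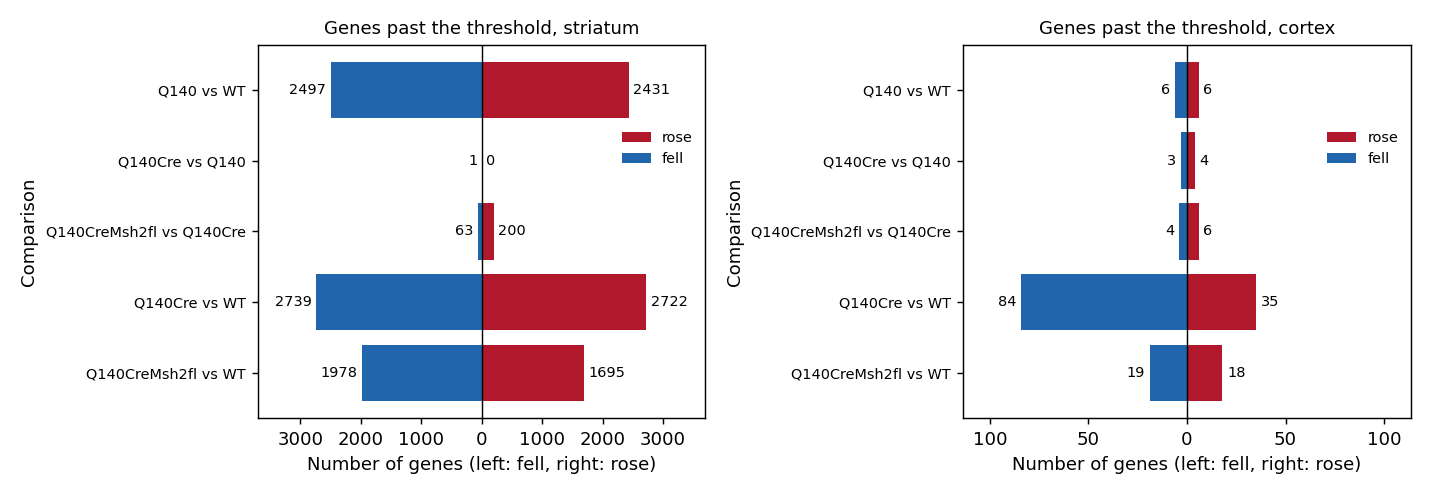
Number of genes that fell (left bars) and rose (right bars) at an adjusted p under 0.05 in each comparison of genotypes, in the striatum and the cortex, each panel with its own axis. Q140 vs WT has 4928 genes in the striatum and 12 in the cortex.

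In the cortex of Q140 against WT few genes differed. Abhd1 (1.46, SE 0.096, adjusted p = 9.68e-13), the lipid transporter Abca8a (0.44), Cgref1 (0.43) and Rab9b (0.19) rose, and Lrrc32 (-0.41), Atraid (-0.31), Tspan2 (-0.28), Enho (-0.21), the kinase inhibitor Camk2n1 (-0.20) and Ngef (-0.11) fell. With Gm2420 (4.29) and Gm6089 (2.60) this made 12 of 18100 genes, 6 higher and 6 lower. Over the 10 other settings the count was 9 to 42, with 35 by DESeq2. Abhd1, Atraid, Cgref1, Gm2420 and Gm6089 lie within 10 Mb of Htt, which holds 1.07% of the tested genes (one-sided Fisher's exact p = 9.76e-08). Oligodendrocyte genes passed as a list (adjusted p = 5.75e-08), with 4 falls adjusted over the list alone, among them Cldn11 (-0.24) and Plp1 (-0.21), as did heat shock genes (6.65e-06; Dnajb1 0.19), astrocytes (0.00851; Slc1a2 -0.16) and cholesterol synthesis (0.0243; Insig1 -0.33). With an estimated correlation the adjusted p was 0.246 for the first 3 and 0.52 for cholesterol synthesis.

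In the cortex of Q140CreMsh2fl against Q140Cre 10 genes passed, 6 higher and 4 lower. Gpatch11 (0.41, SE 0.074), Heatr5b (0.23), Msh2 (0.22), mt-Nd1 (0.22), St3gal2 (0.13) and the predicted gene Gm6969 (1.27) rose, and Cox7a2l (-0.45, SE 0.053), Ttc7 (-0.41, SE 0.053), Cebpzos (-0.41, SE 0.077) and the potassium channel partner Kcnip4 (-0.19, SE 0.035) fell. Apart from Msh2 itself 5 of the 9 lie within 10 Mb of Msh2, against 0.431% of tested genes (one-sided Fisher's exact p = 1.62e-10). Endothelial genes passed as a list (adjusted p = 0.0116, with 4 rises adjusted over the list alone that included Cldn5 at 0.26 and Cdh5 at 0.20) and astrocytes (0.0171), both with adjusted p = 0.288 with an estimated correlation. With plate column in the model 0 genes passed in edgeR, where all 10 had an unadjusted p under 0.05 and the same sign, as the median size went from 0.318 to 0.283 and its SE from 0.049 to 0.076, and DESeq2 called 41 without plate column. The count was 43 without Q140Cre M1, 29 without Q140CreMsh2fl F2 and 6 without Q140Cre M3. The cortical signature of 12 genes gave scores of 0.318 (SD 0.097) in Q140Cre and 0.334 (SD 0.067) in Q140CreMsh2fl, a difference of 0.016 (95% bootstrap interval -0.057 to 0.096, exact permutation p = 0.717). With 1 library left out the difference was -0.015 to 0.062, and it was negative without Q140Cre F1 (-0.005), M3 (-0.013) or M4 (-0.007) or Q140 M1 (-0.015). Of those 12 genes 5 lie within 10 Mb of Htt, so the score rests in part on genes near the altered allele that the compared genotypes share.

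Against WT, 119 cortical genes passed in Q140Cre (35 higher and 84 lower) and 37 in Q140CreMsh2fl (18 higher and 19 lower). In Q140Cre the largest rises included Abhd1 (1.32), the oligodendrocyte gene Enpp6 (0.77), Cdhr3 (0.71), Col2a1 (0.66), Cgref1 (0.45) and Abca8a (0.42), and the largest falls included the vitamin D receptor Vdr (-0.72), Tmem37 (-0.66), Myl4 (-0.52), Gpr153 (-0.50), Plk5 (-0.49) and Rgs9 (-0.47). In Q140CreMsh2fl they included Abhd1 (1.47), Ston1 (0.69), Enpp6 (0.60) and Gpatch11 (0.50) upward, and Kpna2 (-0.55), Cox7a2l (-0.46), Ttc7 (-0.44), Rgs9 (-0.44) and Gpr153 (-0.34) downward. Of 12 oligodendrocyte genes 3 fell in Q140Cre, Plp1 (-0.30), Aspa (-0.34) and Ugt8a (-0.31). In Q140Cre 7 lists passed at the preset correlation, oligodendrocytes (adjusted p = 5.63e-05), cholesterol synthesis (0.000474), endothelial cells (0.0214), and shared SPN genes, cortical excitatory neurons, astrocytes and immediate early genes (0.0082 each). In Q140CreMsh2fl 5 passed, immediate early genes (1.43e-07), oligodendrocytes and microglia (0.000359 each), cholesterol synthesis (0.00171) and cortical excitatory neurons (0.00272). None of these 12 passed with an estimated correlation, where the lowest adjusted p was 0.0998 and 0.0982. The Q140Cre count was 360 without Q140Cre F1, 78 without Q140Cre F4 or WT F4, 74 without Q140Cre M3 and 64 without WT M1, and the Q140CreMsh2fl count was 19 without Q140CreMsh2fl M4, 20 without WT F2 or M2 and 23 without WT M3. DESeq2 called 289 and 57, a fit of the 16 compared libraries called 47 for Q140Cre, and for Q140CreMsh2fl plate column in the model left 3 and FPKM gave 23 and 20.

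The difference between the tissues was tested itself. For Q140 vs WT 2494 of 18965 genes changed differently, 1055 more upward in the striatum and 1439 more downward. Cpne9 measured -2.09 in the striatum and -0.11 in the cortex (difference -1.98, adjusted p = 1.68e-20), the synaptic scaffold Shank3 differed by -0.61, Pde1b by -0.64, Ddit4l by -1.72, Mafa by -2.76, the cannabinoid receptor Cnr1 by -0.94, Ipcef1 by 1.24 and Sfmbt2 by 1.67. For Q140CreMsh2fl vs Q140Cre 12 genes differed, 11 more upward in the striatum and 1 more downward. They were Ttc7 (0.57, adjusted p = 4.18e-06), Fst (0.87, adjusted p = 0.00637), Ryr1 (0.63), Coch (0.48), Sec14l1 (0.22), Vrk1 (0.35), Ngef (0.17), Pde1b (0.19), Arpp21 (0.29), Nrep (0.47), Ddit4l (0.60) and Rpl3-ps2 (-0.51). With the animal as a block, since both tissues came from the same animals, 3127 and 34 genes passed, the latter with 11 of these 12. Msh2 differed by -0.21 (SE 0.054, adjusted p = 0.142, and 0.0768 with the animal as a block).

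The difference between females and males in the striatum was tested for both questions. In edgeR 0 genes passed for Q140 vs WT, with 591 at an unadjusted p under 0.05, a lowest adjusted p of 0.615 and 1 called by DESeq2. For Q140CreMsh2fl vs Q140Cre 0 genes passed in edgeR and 0 in DESeq2, with 690 at an unadjusted p under 0.05 and a lowest adjusted p of 0.993. On simulated counts these tests called 13.4% and 20.9% of the genes changed 1.2-fold, so differences of that size could be missed.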

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

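The tests in this part were chosen only after the results were seen, except the counts of other splits of the libraries, whose predictions were written before.

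Msh2, Htt and Rgs9, the signature score, the library total and the mitochondrial share were each read in the 8 groups of 8 libraries, and 3 of these 48 readings held a library far from the others, where chance gives about 1 in 20 (2.4). Msh2 measured 42.5 CPM in Q140CreMsh2fl cortex F2 against 34.3 to 37.1 in the other 7, Rgs9 6.02 CPM in Q140 cortex M3 against 7.29 to 8.08, and Htt 154 CPM in Q140 striatum M1 against 197 to 207. The striatal and cortical changes differed by their own test at 2494 genes for Q140 vs WT and at 12 genes for Q140CreMsh2fl vs Q140Cre.

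Each count of called genes was set against other splits of the same libraries, of which 60 were drawn, the real one included. In the striatum the real split stood alone among those drawn for Q140 vs WT (4928 genes, 1 of 60, highest other 2627), Q140CreMsh2fl vs Q140Cre (263, 1 of 60, highest other 2), Q140Cre vs WT (5461, 1 of 60, highest other 168) and Q140CreMsh2fl vs WT (3673, 1 of 60, highest other 86). The share of splits argues against chance for these counts, but not against a structure of the samples. A drawn split may keep most libraries in their real groups, and the make-up of the split with 2627 calls was not examined. That count may reflect the Q140 effect itself or a structure of the samples. Among 64 exchanges of 1 library between the groups, which keep most of the real split, 3 called more than the 263. For Q140Cre vs Q140 in the striatum (1 gene) chance cannot be excluded, with 4 of 60 splits as large and a highest other count of 247, which points to a structure of the samples. That 1 gene was Rgs9, named in advance, at -0.36 (SE 0.0449, adjusted p = 3.74e-05), and a count of 1 says little about it. In the cortex the share of splits argues against chance for Q140 vs WT (12, 1 of 60, highest other 1), Q140Cre vs WT (119, 1 of 60, highest other 0) and Q140CreMsh2fl vs WT (37, 1 of 60, highest other 6). For Q140Cre vs Q140 in the cortex (7, 2 of 60, highest other 130) the share of splits was under the 0.05 set in advance, but chance stays open. Another split called far more genes than the real one, which points to a structure of the samples. The count was also 0 without any of 4 single libraries (Q140Cre F4 or M3, Q140 F1 or M4). Chance cannot be excluded for Q140CreMsh2fl vs Q140Cre in the cortex (10, 3 of 60), where the highest other count of 192 points to such a structure too. For the differences between tissues the share in 40 splits each argues against chance (2494, 1 of 40, highest other 766, and 12, 1 of 40, highest other 2). The count of 766 may likewise come from a split that keeps most animals in their real groups or from a structure of the samples, which was not examined. For the differences between sexes (0 genes in edgeR for each, with 591 and 690 at an unadjusted p under 0.05 and 1 and 0 in DESeq2) 60 of 60 splits were as large. The highest other counts were 32 and 1, and the make-up of the split with 32 calls was not examined. With a real count of 0 every split is as large by construction, so these splits say nothing about chance.

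The first pattern weighed is the lower Q140 signature score of Q140CreMsh2fl against Q140Cre in the striatum (-0.066), with its 263 called genes. Neighbouring tissue in the dissection was weighed with scores of 2 lists, choroid plexus and ependyma, and thalamic and other neighbouring neurons. Tissue of these 2 kinds was argued against for the score, which differed by -0.067 (SE 0.01) with both in the model. It was not argued against for the whole count, as 113 genes passed there and 109 of the 263 were kept. Cortical tissue was not in that model and stays open. Striatal Slc17a7 measured 1.87 to 21.1 CPM in Q140Cre libraries and 2.66 to 18.5 in Q140CreMsh2fl libraries. A higher share of spiny projection neurons cannot be told apart from a return towards WT, since either would lower the genes that had risen in Q140 outside the SPN lists (-0.052, SE 0.0074), and markers of 7 other cell types, which a higher share would lower at least as much, measured 0.013 (SE 0.032), above those genes by 0.066 (SE 0.035), which is within 2 SE for the 7 lists together and beyond it for astrocytes (0.091, SE 0.037) and mural cells (0.182, SE 0.049) among them. Plate column was argued against for the score (-0.066, SE 0.015 with plate column in the model, though this rests on few libraries). For the count it cannot be told apart from genotype. Exchanging Q140CreMsh2fl F4, in the first column, with Q140Cre M1, in the fourth, set the fourth column against the others and gave 374 calls. Of the 8 exchanges within a column 1 gave 404 and the other 7 at most 76. The median of all 64 exchanges was 1.5, with 3 above the real 263. With plate column in the model 0 genes passed, as the median size went from 0.221 to 0.172 and its SE from 0.051 to 0.078. Floxed Msh2 may therefore be a candidate explanation for the lower score, as a hypothesis found and tested on the same data. It stands beside the share of these neurons, cortical tissue in the dissection, and a different litter, cohort, strain or mitochondrial background of the floxed line. Cortical tissue and such differences of the line were not tested.

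The second pattern is that called genes lay near the altered loci. Linked DNA that came with the altered allele is a candidate explanation, since 5 of 12 called genes lay within 10 Mb of Htt in the Q140 cortex (Fisher's exact p = 9.76e-08), 5 of 9 near Msh2 in the Q140CreMsh2fl cortex (1.62e-10) and 2 of 6 near Rgs9 in the Q140Cre cortex (0.00443, or 0.0148 adjusted over the 30 tests run, from a count of 7 that fell to 0 without any of 4 single libraries). Deletion of Msh2 in cells that express Rgs9 would put these changes in the striatum. Of the 7 genes near Msh2 called in the striatum 6 had a cortical change of the same sign beyond 2 SE, which argues against deletion as the cause for these 6. For Foxn2 it did so only narrowly (0.14, SE 0.068). Ttc7 fell in the cortex (-0.41, SE 0.053) with no call in the striatum. Strn measured 0.26 in the striatum and 0.02 in the cortex. Its tissue difference had adjusted p = 0.07, and 0.0422 with the animal as a block. Strn had fallen in the Q140 striatum (-0.48, adjusted p = 4.8e-10). Like Foxn2 it was among the 227 called genes with the opposite sign to Q140 vs WT, so whether its change belongs to the locus stays open. Sequence differences that change how reads align, and an effect of each altered allele on its neighbours, were not tested and stay open.

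The third pattern is the Msh2 count itself, higher in Q140CreMsh2fl than in Q140Cre in the cortex (0.22) and level in the striatum (0.01). Plate column was argued against, with a cortical difference of 0.23 (SE 0.065) with plate column in the model, though this too rests on few libraries. A loss of Msh2 message in part of the striatal cells on top of a raised level in all cells stays open, since the striatal minus cortical difference of -0.21 (SE 0.054, adjusted p = 0.142, and 0.0768 with the animal as a block) restates the pattern and counts per exon, which would show the excised part, were not available.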

How the results depend on the processing

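The settings without the 3 striatal libraries that stand apart and with neighbour tissue scores as covariates were chosen only after the data were seen, and the others were planned. Where a count below moved, the cause was not tested. Q140 vs WT in the striatum had 4256 to 6653 calls in 12 of 12 settings (4605 to 5109 with 1 library left out), and Q140Cre vs WT 5021 to 7430. The striatal signature difference was -0.163 to -0.062 in 7 of 7 settings and -0.072 to -0.06 with 1 library left out. On log2(FPKM + 0.1), which has no TMM scaling, 76.3% of the calls of Q140 vs WT in the striatum were rises (5075 against 1578 falls) and the median change of all genes was 0.066, and 76% on log2(FPKM + 1).

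With plate column the counts were 0 for Q140CreMsh2fl vs Q140Cre in the striatum (263) and 0 in the cortex (10, where the median size went from 0.318 to 0.283 and its SE from 0.049 to 0.076), 1339 and 3 for Q140CreMsh2fl vs WT (3673 and 37) and 105 for Q140Cre vs Q140 in the cortex (7). DESeq2 gave 3 for Q140Cre vs Q140 and 449 for Q140CreMsh2fl vs Q140Cre in the striatum, 35, 241, 41, 289 and 57 for the 5 cortical comparisons in the order Q140 vs WT, Q140Cre vs Q140, Q140CreMsh2fl vs Q140Cre, Q140Cre vs WT and Q140CreMsh2fl vs WT, 26 for the tissue difference of Q140CreMsh2fl vs Q140Cre and 1 for the sex difference of Q140 vs WT. Without a low-count filter Q140Cre vs Q140 in the striatum gave 4 and Q140 vs WT in the cortex 20, and with the stricter filter Q140Cre vs Q140 in the cortex gave 23. With only the 16 libraries compared the cortex gave 42 for Q140 vs WT, 4 for Q140CreMsh2fl vs Q140Cre and 47 for Q140Cre vs WT. FPKM gave 3 and 3 for Q140Cre vs Q140 in the cortex and 23 and 20 for Q140CreMsh2fl vs WT in the cortex. Without the 3 libraries that stand apart the counts were 4 for Q140Cre vs Q140 and 395 for Q140CreMsh2fl vs Q140Cre in the striatum (240 of the 263 kept) and 27 for its tissue difference. With neighbour tissue scores Q140CreMsh2fl vs Q140Cre gave 113 (109 of the 263 kept).

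With 1 library left out the counts were 1 to 2 for Q140Cre vs Q140, 86 to 382 for Q140CreMsh2fl vs Q140Cre and 3293 to 3599 for Q140CreMsh2fl vs WT in the striatum, and 10 to 18, 0 to 349, 6 to 43, 64 to 360 and 19 to 40 in the cortex, in the order given for DESeq2. The cortical signature difference was -0.015 to 0.062, and it turned negative without Q140Cre F1 (-0.005), M3 (-0.013) or M4 (-0.007) or Q140 M1 (-0.015). Lists that passed with an estimated correlation numbered 4, 0, 3, 4 and 4 in the striatum and 0 in each cortical comparison. Msh2 in Q140CreMsh2fl vs Q140Cre in the striatum turned to -0.004 on both FPKM scales, Htt in Q140CreMsh2fl vs WT in the striatum to 0.025 and 0.023, and Htt in Q140CreMsh2fl vs Q140Cre in the cortex to 0.001 with RLE, none past the threshold.

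The replicate block was run with the numbers of the labels, which mark different animals in different genotypes. Same-numbered libraries correlated at -0.3 to 0.32, and in no comparison did every pair exceed 0.1, so the numbers do not pair the samples. With the block the counts were 4884, 1, 219, 5451 and 3664 in the striatum and 18, 0, 9, 127 and 35 in the cortex, 0 and 0 for the sex differences, and the signature differences were -0.066 and 0.016. With the animal as a block, which does pair the tissues, the tissue differences were 3127 and 34. Within 1 tissue each animal has 1 library, so that block applies to no other count. The cortical signature of at least 1.5-fold was not computed, as it held fewer than 10 genes.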

Other observations

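The values in this part were chosen for report only after the data were seen.

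Some transcripts outside the lists differed between Q140CreMsh2fl and Q140Cre, not all in both tissues or in the same direction. Gm6969, a predicted gene, measured 38.5 ± 4.17 CPM in the striatum against 16.8 ± 6.29 in Q140Cre, and 33.5 ± 3.31 against 13.8 ± 5.33 in the cortex (SD, n = 8). The mitochondrial mt-Nd1, a subunit of respiratory complex I, measured 8482 ± 491 CPM against 7260 ± 610 in the striatum and 5997 ± 350 against 5152 ± 438 in the cortex. Another subunit gene, mt-Nd5, measured 4674 ± 460 against 5467 ± 286 CPM in the striatum and 3424 ± 158 against 3736 ± 330 in the cortex, where it did not pass (adjusted p = 0.207). Cox7a2l measured 55.6 ± 6.62 against 74.8 ± 4.32 CPM in the striatum and 48 ± 4.26 against 65.5 ± 5.59 in the cortex. Near Htt, Gm6089 measured 4.7 ± 0.596 CPM in the Q140 striatum and 0.487 ± 0.196 in WT.

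Some libraries stood apart within their groups. Across genes, which are not independent replicates, the Spearman correlation of a library's deviations from its group with gene length was -0.52 in Q140 striatum M1, -0.47 in Q140Cre striatum F1 and -0.45 in Q140Cre cortex F2. Xist measured on average 0.787 CPM in male Q140CreMsh2fl striatum and 1.01 in male Q140CreMsh2fl cortex, and 0.0919 to 0.1825 as a mean in males of the other groups. Of the 263 genes called in the striatum between Q140CreMsh2fl and Q140Cre, 36 were not in the Q140 signature, Cox7a2l among them.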
